A study of Bos taurus with 14 samples.

How the data were processed

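RNA of 14 whole bovine conceptuses collected on Day 15 of gestation was measured, each on 1 Affymetrix bovine expression array. The values used here are log2 expression values of probe sets, made by the authors with RMA in Affymetrix Expression Console per the submitters' processing notes; software versions, and which arrays were normalised together, are not given in the sources used here. RMA subtracts background, quantile-normalises the arrays and summarises the probes of a probe set on the log2 scale, so small differences at low intensity are compressed and a shift of all genes together is removed. Per the labels' protocols, 250 ng of total RNA per conceptus was labelled with biotin. The deposited table held 24128 probe sets with values from 2.235 to 14.61 and 0 missing values. Array medians lay between 5.62 and 5.716, and the correlation between any pair of arrays across probe sets lay between 0.9838 and 0.9967. Arrays carry no read depth; their number limits the precision, and the 95% interval of a log2 difference reached, at the median probe set, to each side by 0.21 for grade, 0.198 for length and 0.178 for sex.

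The 112 array control probe sets were left out, which left 24016 probe sets. Gene symbols came from the platform annotation, in which 13292 probe sets had 1 symbol, 86 had several and 10638 had none; a probe set with several symbols or none was counted and not named. Of the named probe sets, 13263 matched the RefSeq gene table of assembly ARS-UCD2.0 by Entrez number, and 0 symbols changed. That table was used only for names and for which genes lie on the sex chromosomes; no coordinates or genome sequence were used here. The named probe sets covered 9155 genes, of which 2913 had more than 1 probe set. Each gene was represented by its probe set with the highest mean over the 14 arrays, and probe sets of a gene that disagreed are named in the results.

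Groups came from the labels. Embryos were graded by morphology at recovery on Day 6.5; 11 conceptuses came from Grade 1 embryos and 3 from Grade 3 embryos. Of the Grade 1 conceptuses, 5 were marked long, 5 short and 1 carried no length. For Grade 1 short replicate 1, one label gives long and another short; the length characteristic was used because it yields the 5 and 5 that the design text states. The design text gives 4 Grade 1 conceptuses for its comparison of grades without naming them, so all 11 were used and 100 of the 120 possible sets of 4 that hold the conceptus with no length were tried as an alternative. The labels give 6 males and 8 females. Sample titles share 7 prefixes whose meaning is not stated. Of these, 2 hold both lengths, 0 hold both grades, and most hold 1 sex only. Embryos were transferred in groups of 2 to 6, and the labels do not say which conceptuses shared a recipient or a dam, so p-values measure the spread between these conceptuses and treat them as independent.

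Grade 3 was compared with Grade 1 (3 and 11), long with short within Grade 1 (5 and 5), and male with female with grade as a covariate (6 and 8). Each comparison used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with Benjamini-Hochberg adjustment over the 24016 probe sets and a threshold of 0.05; tests were two-sided. On simulated data with 200 of 24016 probe sets changed, the fit recovered 26%, 72%, 94% and 100% of changes of 1.25, 1.5, 2 and 3 fold with the group sizes of the grade comparison, and 3.95% of its calls were false. With the sizes of the length comparison it recovered 28%, 80%, 100% and 100%, with 3.14% false, and with those of the sex comparison 40%, 82%, 96% and 100%, with 2.45% false. Only random variation between arrays was simulated, independent between probe sets, and the changed ones were drawn from all probe sets, dim ones included. The shares are thus averages and do not hold for a probe set with a large spread. In the grade comparison ASZ1, at 2.64 fold with an SE of 0.51 (log2), had adjusted p = 0.927 in limma.

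The test, the samples, the gene lists, the rule for named genes and all alternatives except those named as later were chosen before the data were examined. There were 26 lists: trophectoderm lineage; interferon tau and trophoblast Kunitz proteins; pregnancy-associated glycoproteins; binucleate trophoblast and placental hormones; epiblast and pluripotency; hypoblast and visceral endoderm; gastrulation and mesoderm; extracellular matrix and stroma; prostaglandin synthesis and transport; lipid metabolism and PPAR; cholesterol synthesis; glucose and amino acid transport; glycolysis; oxidative phosphorylation; cell cycle and proliferation; apoptosis and cell stress; interferon-stimulated genes; adhesion, protease and actin remodelling; growth factor signalling; imprinted genes. The others were markers of endometrial epithelium, blood and immune cells, erythroid cells, endothelium, Y-linked genes and X-linked genes tied to inactivation. The 23 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with camera at the estimated correlation and with fry as alternatives, and adjusted over the 23 lists. fry tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes.

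Named genes followed a fixed rule. Per comparison these were the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold, filled up to 6 with the smallest unadjusted p among genes changed by at least 1.5 fold where fewer passed. For each list, up to 4 members past the threshold were named, or else the 1 member with the smallest p. The interferon tau probe set was always named, and for sex also XIST, the Y-linked genes and the 5 genes with the smallest p outside the sex-linked lists. Leading probe sets without a symbol are counted and their IDs are not printed here. Scores of a list are means over its genes of log2 values centred on their mean over the arrays. Only the scores of the cholesterol synthesis list were compared between groups by exact permutation tests, a choice made after the results were seen.

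Alternatives covered a filter on dim probe sets, quantile normalisation once more, centring of arrays, an intensity trend with a robust prior, a test without moderation, 1 probe set per gene, other thresholds, sex as a covariate, the title prefix as a random or fixed block (duplicateCorrelation, statmod 1.5.0), other choices of the Grade 1 conceptuses, the conceptus whose labels disagree counted as long or left out, and each conceptus left out in turn. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.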

Results

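Expression was profiled in 14 Holstein conceptuses, the embryo proper with its surrounding membranes, recovered from recipient heifers on Day 15, when the trophoblast of cattle elongates. The embryos had been sired by 1 bull, collected on Day 6.5 and sorted by morphological grade before transfer. The arrays gave log2 values for 24016 probe sets and 9155 named genes in 11 conceptuses from Grade 1 embryos and 3 from Grade 3 embryos. Within Grade 1, 5 conceptuses were long, 5 were short and 1 had no recorded length. In a principal component analysis of all 14 arrays, the first component held 28.85% of the variance, and long conceptuses scored 5.89 to 31.58 on it against -38.4 to -1.829 for short ones.

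The first comparison asked whether conceptuses from embryos of poorer morphology differed on Day 15 from those of good embryos. No single gene passed the test between the 3 Grade 3 and the 11 Grade 1 conceptuses. Interferon tau, the trophoblast signal by which ruminants recognise pregnancy, did not pass: IFNT2 measured 14.51 ± 0.05 (SD, n = 3) in Grade 3 and 14.53 ± 0.07 (SD, n = 11) in Grade 1, a log2 difference of -0.03 with adjusted p = 0.999 in limma. The highest value on any array, 14.61, was that of IFNT2 itself in Grade 1 long replicate 1. A ceiling there could compress a difference, but these values cannot show whether one was reached. The 14 measured genes of cholesterol synthesis were all lower on average in Grade 3, by a median log2 difference of -0.16, and this was the only gene list past camera at the preset correlation (adjusted p = 0.00535; adjusted p = 0.961 with an estimated correlation and 0.957 with fry). None of the 14 passed alone, over all genes or adjusted over the list alone; FDFT1, squalene synthase, differed most clearly at -0.28 ± 0.14 (SE).

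limma called 0 of 24016 probe sets for grade, with a smallest adjusted p of 0.611; 1215 had an unadjusted p under 0.05, where chance gives 1200.8. In 133 probe sets (0.554%) the values of the 2 groups did not overlap, against 0.549% by chance. The genes with the smallest p among those changed by 1.5 fold or more, none of which passed, included ASZ1, a germ cell gene of the piRNA pathway, at 1.40 ± 0.51 (log2, SE) in Grade 3 over Grade 1. AP1M2, an adaptor subunit of epithelial clathrin coats, stood at 0.77 ± 0.18 (SE, adjusted p = 0.777), and NUDT10, MXI1, SLC34A2 and PARP12 at 0.99, 0.82, 0.66 and 0.63. On the other side were the calcineurin regulator RCAN2 (-0.92), the heparin-binding growth factor MDK (-0.90), the glucuronosyltransferase UGT1A6 (-0.88), the scramblase family member PLSCR4 (-0.85), CA8 (-0.72) and PIGZ (-0.61). Leaving out Grade 3 replicate 1 gave 2 called probe sets and leaving out Grade 1 long replicate 5 gave 1; without the latter AP1M2 passed at 0.86 (adjusted p = 0.00298).

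In the other 22 tested lists the smallest camera adjusted p for grade was 0.124, for the X-linked genes (median -0.14; 2 of 3 Grade 3 conceptuses were male, against 4 of 11 in Grade 1). Interferon-stimulated genes, which respond to interferon tau in the uterus, followed with a median of 0.05 over 22 genes (adjusted p = 0.224), led by ISG15 at 0.26. Growth factor signalling held the only gene called when adjusted over the list alone, EGF, at 0.32 ± 0.08 (SE) and a level of 4.33 against 4.01. The leading members of the remaining lists did not pass either. Among lineage and placental lists these were DLX4 (-0.33), PAG4 (0.19), PRP6 (0.13), TKDP2 (-0.25), SOX2 (-0.16), MEIS2 (-0.09) and LAMB1 (0.30), and among matrix, adhesion and imprinted genes FN1 (0.40), TJP1 (0.43) and MEG3 (0.16). For metabolism, transport, cycle and stress they were SLC2A8 (0.50), SLC16A3 (-0.46), ACACA (0.23), NDUFS4 (0.07), AKR1C3 (-0.10), CENPA (0.16) and GADD45B (0.47). For markers of other cell types and sex-linked genes they were PAX8 (0.19), CD4 (0.12), SLC4A1 (0.11), TEK (-0.18), TSPY (0.11) and KDM6A (-0.47). Probe sets of TSPY, SLC16A3, PRP6, FDFT1, KDM6A and MEIS2 differed among themselves in sign. Median, mean and test differed in sign for the binucleate, lipid and endothelium lists.

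The cholesterol list lost its call in several settings. Besides the estimated correlation and fry, it had adjusted p = 0.107 with sex as a covariate (mean -0.13), 0.0787 with the probe set of smallest p, and 0.158 (mean -0.13) without Grade 3 replicate 1. Scored per conceptus, the list averaged -0.13 ± 0.07 (SD, n = 3) in Grade 3, -0.15 ± 0.05 (SD, n = 5) in short Grade 1, 0.26 ± 0.14 (SD, n = 5) in long Grade 1 and -0.13 in the conceptus with no length. By exact permutation, Grade 3 differed from long Grade 1 by -0.39 (p = 0.0179, the smallest that 3 against 5 can give) and from short Grade 1 by 0.02 (p = 0.554). Against all 11 Grade 1 conceptuses the difference was -0.16 (exact p = 0.299).

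**Figure D1:**
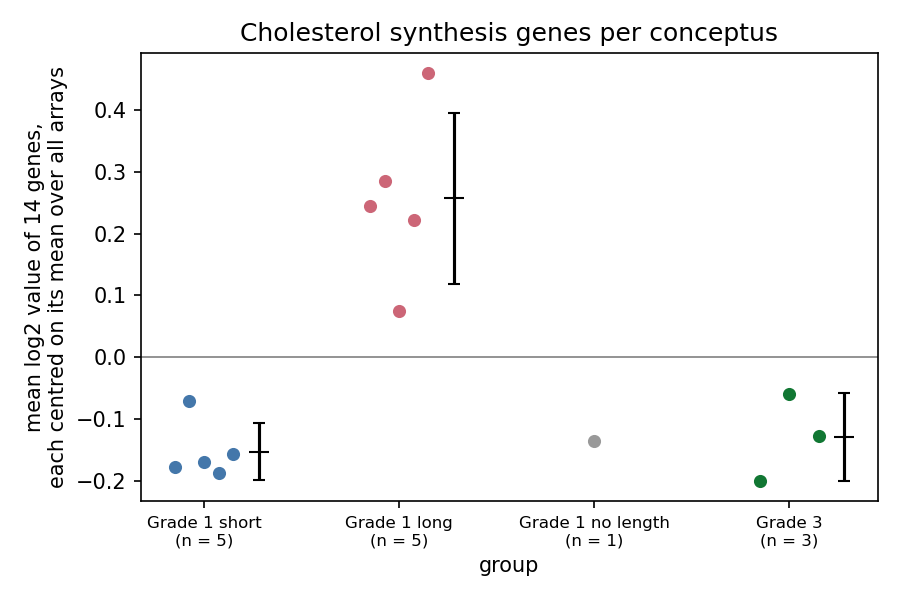
Score of the 14 cholesterol synthesis genes per conceptus (vertical axis, mean centred log2 value) by group; points are conceptuses and bars the mean ± SD beside each group of more than 1. The 3 Grade 3 conceptuses lie between -0.20 and -0.06, the short Grade 1 conceptuses between -0.19 and -0.07, and the long ones between 0.07 and 0.46.

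The second comparison asked what distinguished long from short conceptuses of the same embryo grade. Long conceptuses carried several times the signal of muscle creatine kinase, a pregnancy-associated glycoprotein and a p53-induced oxidoreductase: CKM rose by 3.48 ± 0.56 (log2, SE; 11.1 fold), PAG12 by 3.15 ± 0.56 (8.90 fold) and TP53I3 by 3.13 ± 0.38 (8.77 fold), with 5 conceptuses per group. The platelet-activating factor acetylhydrolase PLA2G7, the cytokine IL6 and the actin-binding protein TAGLN rose by 2.82, 2.44 and 2.31. Genes lower in long conceptuses included the proton pump subunit ATP6V0D2 (-1.90 ± 0.33, SE), the growth factor receptor PDGFRA (-1.80 ± 0.21), the iodide symporter SLC5A5 (-1.71 ± 0.18), the aquaglyceroporin AQP3 (-1.66 ± 0.17), SYBU (-1.53 ± 0.28) and GSDMC (-1.41 ± 0.26). Of the cholesterol synthesis genes 8 of 14 rose, and of the cell cycle genes 5 of 28 fell, each by less than these leading genes. Interferon tau did not pass: IFNT2 was 14.58 ± 0.02 in long and 14.48 ± 0.08 in short conceptuses (SD, n = 5, limma adjusted p = 0.363). Its value in long replicate 1, 14.61, was the highest on any array, so a compressed difference is possible.

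**Figure D2:**
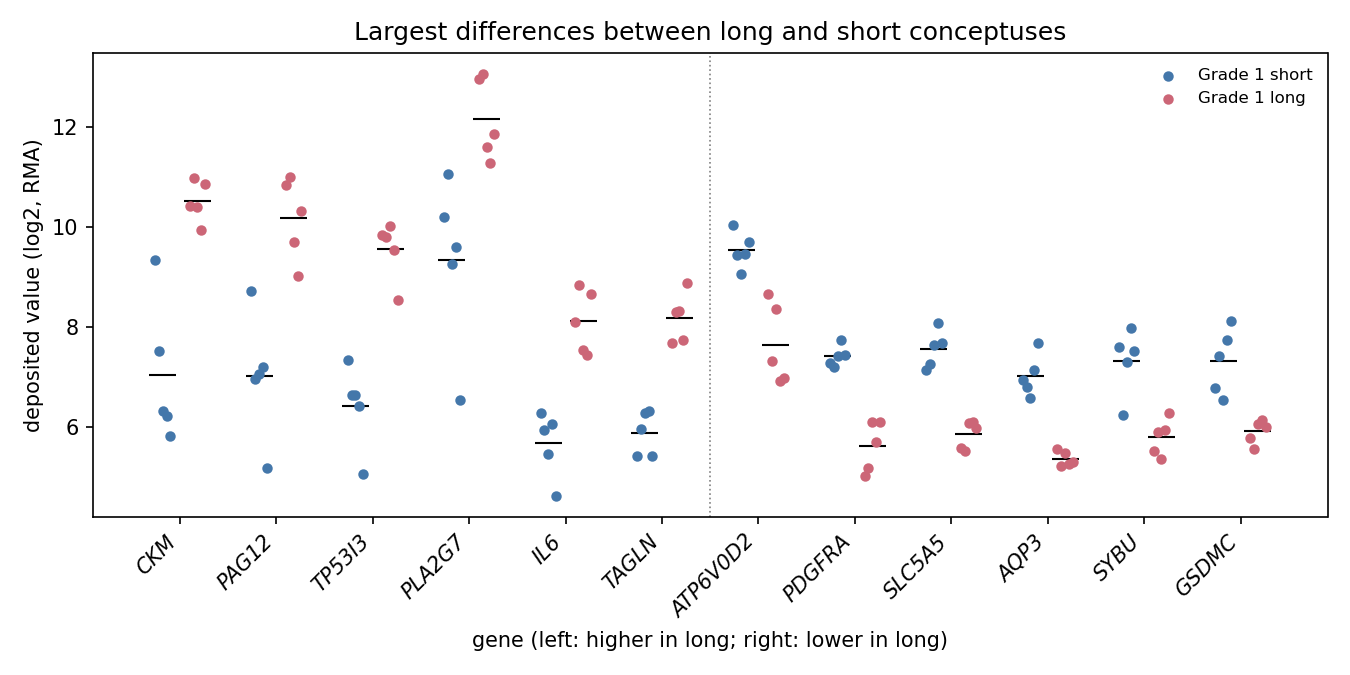
Log2 values (vertical axis) of the 6 genes that rose most and the 6 that fell most in long against short Grade 1 conceptuses; each point is a conceptus and each line a group mean. CKM averaged 10.52 in long and 7.05 in short conceptuses, PDGFRA 5.62 and 7.42.

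In all, 1577 of 24016 probe sets passed in limma, 648 higher and 929 lower in long conceptuses. They covered 345 genes higher and 629 lower, and 2 genes with probe sets in both directions are counted in both numbers. Of the called probe sets, 499 had no single symbol. The excess of lower calls was kept with arrays centred (599 higher, 949 lower). It turned with quantile normalisation once more (743 and 723), the conceptus whose labels disagree counted as long (270 and 222), the title prefix as a fixed block (64 and 48) and the threshold of unadjusted p under 0.01 and 1.5 fold (364 and 190). Most differences were small: 1144 of the called probe sets changed by less than 1.5 fold, while 105 rose and 29 fell by 2 fold or more. The values of the 2 groups did not overlap in 2022 probe sets (8.42%, against 0.794% by chance), 1279 of them called. The count fell to 655, 532, 914 and 510 without Grade 1 long replicates 1, 2, 4 and 5, and to 460 and 704 without short replicates 4 and 5. It was 112 with the title prefix as a fixed block, where only 2 prefixes inform the contrast, 492 with the conceptus whose labels disagree counted as long, and 468 without the 2 short conceptuses that stood most apart, an alternative chosen after the data were seen. Of the 49 named genes that passed, 15, 14 and 23 passed in these 3 settings. Inside the prefix with 2 long and 1 short conceptus, 28 of the 32 probe sets called from the other conceptuses changed the same way (87.5%), and inside the prefix with 1 long and 2 short, 137 of 145 did (94.5%).

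Of the 14 measured cholesterol synthesis genes, 8 rose and 0 fell in long conceptuses (9 when adjusted over the list alone), with a median log2 difference of 0.40 (camera adjusted p = 9.74e-09; p = 0.0176 and adjusted p = 0.34 with an estimated correlation). The sterol demethylase CYP51A1 rose by 1.11 ± 0.15 (SE, adjusted p = 0.00902), HMGCS1, which makes HMG-CoA, by 0.67 ± 0.10, MSMO1 by 0.57 ± 0.10 and NSDHL by 0.44 ± 0.09. For the list fry gave adjusted p = 0.00302, and the camera call at the preset correlation held with each conceptus left out. NSDHL lost its call in 2 of those 10 fits, with adjusted p = 0.0514 without Grade 1 short replicate 4.

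Of 28 cell cycle genes, 5 fell and 0 rose (14 adjusted over the list alone; median -0.16, camera adjusted p = 0.00665; adjusted p = 0.471 with an estimated correlation). The replication licensing gene MCM5 fell by 0.39 ± 0.07 (SE), the cyclin CCNE2 by 0.43 ± 0.08, CDC6 by 0.31 ± 0.08 and the thymidylate synthase TYMS by 0.22 ± 0.06. The list had adjusted p = 0.00302 with fry. TYMS and CDC6 each lost the call in 9 of 10 fits with 1 conceptus left out, with a highest adjusted p of 0.0901 without long replicate 1 and 0.0956 without short replicate 5.

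Few fatty acid and prostaglandin genes passed. In the lipid and PPAR list, 2 of 31 genes rose and 1 fell (4 and 1 adjusted over the list alone; median 0.12, camera adjusted p = 0.0362; adjusted p = 0.471 with an estimated correlation): the fatty acid elongase ELOVL5 rose by 1.89 ± 0.29 (SE) and the acyl-CoA synthetase ACSL5 by 0.86 ± 0.17, and the fatty acid carrier FABP7 fell by 0.87 ± 0.18. In the prostaglandin list, 3 of 16 genes rose (5 higher and 1 lower adjusted over the list alone). These were PLA2G7, the transporter SLCO2A1 (1.37 ± 0.35) and the prostacyclin synthase PTGIS (0.90 ± 0.24). PLA2G7 rose most, by 2.82, and as platelet-activating factor acetylhydrolase is not itself a prostaglandin enzyme. The list had a median of 0.13 and camera adjusted p = 0.0362, or 0.471 with an estimated correlation. Both lists had adjusted p = 0.15 with fry. The prostaglandin call was lost without Grade 1 long replicates 1 and 3 or short replicates 3 and 4 (adjusted p = 0.0845, 0.0594, 0.0574 and 0.0735), and the lipid call without long replicates 1 and 3 or short replicate 4 (0.0507, 0.07 and 0.0558). FABP7 missed the threshold without long replicate 5 (adjusted p = 0.051). PLA2G7, SLCO2A1 and PTGIS lost theirs in 7, 8 and 8 of 10 fits, with a highest adjusted p of 0.0978 (without long replicate 2), 0.101 (long replicate 5) and 0.111 (long replicate 2).

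Placental genes moved unevenly. PAG12 was the only one of 19 pregnancy-associated glycoproteins to pass, also when adjusted over the list alone, while the list's median was 0.06 (camera adjusted p = 0.0362, and 0.471 with an estimated correlation). That call was lost without short replicates 1 and 4 or long replicates 3 and 4 (adjusted p = 0.0553, 0.061, 0.0867 and 0.0563). PAG12 averaged 10.18 in long and 7.03 in short conceptuses. PAG4 averaged 3.28 in Grade 1, PAG15 2.60 in males and 2.71 in females, and the hormone gene PRP6 2.85 in Grade 1. The lowest value of any probe set was 2.235. Members this dim could hardly show a difference, so 1 of 19 does not tell uneven regulation from missing signal. Levels of the other members are not given here. Among 19 genes of binucleate cells and placental hormones, the aromatase CYP19A1 alone passed, over all genes and over the list alone, rising by 1.86 ± 0.37 (SE); its call was lost without short replicate 4 (adjusted p = 0.0546). The list had a median of 0.05 and camera adjusted p = 0.0574, and fry adjusted p = 0.0289. TKDP2, a Kunitz-type trophoblast protein, rose by 0.95 ± 0.23 as 1 of 4 measured genes of its list (2 over the list alone; too few for a list test). Of 14 trophectoderm genes, TFAP2A rose by 0.38 ± 0.10 and ASCL2 fell by 0.49 ± 0.13, with 3 higher and 3 lower over the list alone and camera adjusted p = 0.883. Of 20 imprinted genes, NDN, also known as necdin, fell by 1.35 ± 0.20 together with ASCL2 (1 higher and 2 lower over the list alone; camera adjusted p = 0.883). TFAP2A and ASCL2 lost the call in 8 and TKDP2 in 7 of the 10 fits with 1 conceptus left out, with adjusted p = 0.0982, 0.102 and 0.0822 without long replicate 2.

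Of 27 hypoblast and visceral endoderm genes, 6 rose and 1 fell (7 and 2 over the list alone; median 0.04, camera adjusted p = 0.0826). The signalling ligand BMP2 rose by 2.13 ± 0.32 (SE), the retinol carrier RBP4 by 1.30 ± 0.24 and the apolipoprotein APOA1 by 0.59 ± 0.10, whereas PDGFRA was the member that fell. The DNA methyltransferase DNMT3B fell by 0.39 ± 0.09, and all 3 measured epiblast genes were lower when adjusted over the list alone. Of 7 gastrulation and mesoderm genes none passed (2 higher and 2 lower over the list alone; median -0.11, camera adjusted p = 0.996); SNAI1 stood at -0.78 ± 0.21 with adjusted p = 0.051. In the matrix and stroma list 3 of 19 rose, also over the list alone: TAGLN, SPARC (0.47 ± 0.12) and THY1 (0.40 ± 0.11); its median was -0.00375 and its mean 0.17, with camera adjusted p = 0.105. DNMT3B, SPARC and THY1 lost their calls in 7, 8 and 9 of 10 fits, with a highest adjusted p of 0.0795 (without long replicate 5), 0.0971 (short replicate 4) and 0.112 (long replicate 2).

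Other functional lists changed in few members. The integrin ITGAV (0.55 ± 0.14, SE) and the tropomyosin TPM4 (0.82 ± 0.20) rose among 35 adhesion genes, also over the list alone (camera adjusted p = 0.167). IGFBP7, an insulin-like growth factor binding protein, rose by 1.81 ± 0.24 as 1 of 35 growth factor genes by both counts (0.0756), and the glucose transporter SLC2A3 by 0.95 ± 0.21 as 1 of 18 transport genes (0.883). The lactate transporter SLC16A3 fell by 0.58 ± 0.11 as 1 of 18 glycolysis genes (0.0993), the complex I subunit NDUFS3 by 0.32 ± 0.08 as 1 of 33 oxidative phosphorylation genes (0.0826), and IRF7 by 0.31 ± 0.07 as 1 of 22 interferon-stimulated genes (0.883), each by both counts. Of 28 apoptosis and stress genes, BCL2 fell by 0.35 ± 0.07 in its brightest probe set (the other 4 had the opposite sign), BCL2L1 by 0.40 ± 0.08 and SOD2 by 0.39 ± 0.08, by both counts (0.764); BCL2L1 restrains cell death. With 1 conceptus left out in turn, ITGAV and IRF7 lost the call in 8, TPM4 and NDUFS3 in 7, SLC2A3 in 5 and SOD2 in 1 of 10 fits, with a highest adjusted p of 0.106, 0.0807, 0.0943, 0.0812, 0.0618 and 0.0527. Those values came without long replicate 2 for ITGAV, TPM4 and NDUFS3, long replicate 5 for IRF7 and short replicate 4 for SLC2A3 and SOD2.

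Lists of marker genes for cells that could accompany a flushed conceptus did not pass camera, although single genes passed. In the endothelium list PECAM1 rose by 0.99 ± 0.14 (SE) and SOX18 fell by 0.84 ± 0.15 among 13 genes, by both counts (camera adjusted p = 0.57). CD8A fell by 0.84 ± 0.20 as 1 of 18 blood and immune genes by both counts (0.883), and lost the call in 7 of 10 fits with 1 conceptus left out, with adjusted p = 0.0771 without long replicate 5. None of 10 endometrial genes or 11 erythroid genes passed by either count (0.883 for both); MUC1 stood at 0.55 (adjusted p = 0.128) and GYPC at -0.19 (0.288). X-linked genes did not pass, KDM6A at 0.41 (list 0.679), and of 2 Y-linked genes TSPY stood at 0.03; the long group held 4 females and 1 male, the short group 3 and 2. Median, mean and test differed in sign for the matrix, endometrial, transport, adhesion, interferon-stimulated and erythroid lists. For BCL2 only the brightest of 5 probe sets fell, and the other 4 had the opposite sign, 1 of them called (0.24, adjusted p = 0.0493) and 1 at a level of 10.84 just short of it (0.24, adjusted p = 0.0553), so its direction is not settled. A dimmer probe set of CKM measured 0.13 (adjusted p = 0.376), and other probe sets of PDGFRA, SLC16A3, NDUFS3, DNMT3B, CYP19A1, IRF7, KDM6A and TSPY had the opposite sign without passing.

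**Figure D3:**
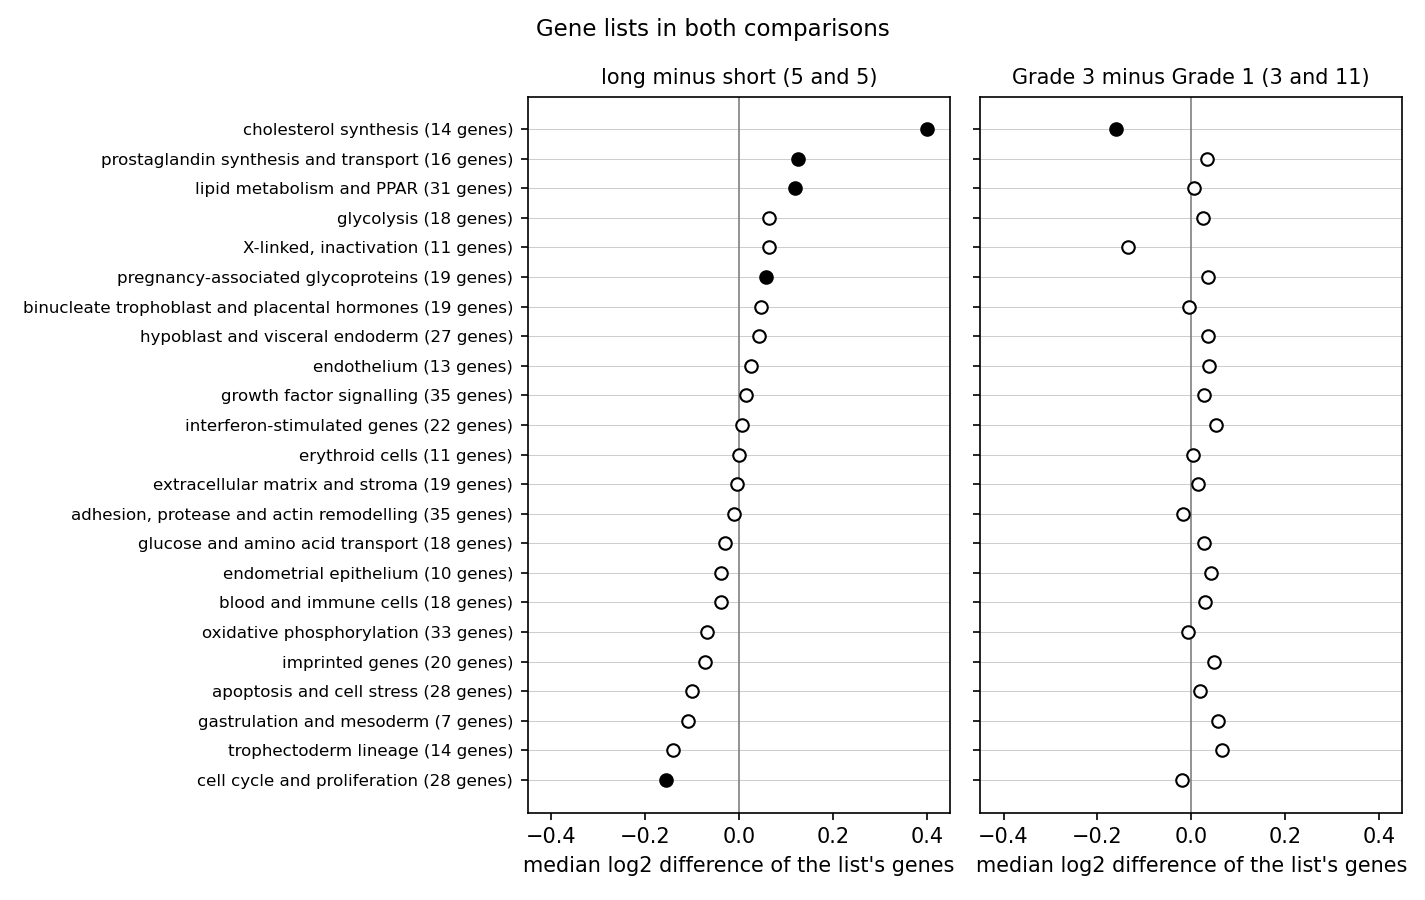
Median log2 difference (horizontal axis) of each of the 23 tested gene lists for long minus short and for Grade 3 minus Grade 1; filled points passed camera at the preset correlation, open points did not. Cholesterol synthesis has a median of 0.40 in the left panel and -0.16 in the right one.

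The third comparison set the 6 male against the 8 female conceptuses, which also checks the labels. XIST, the RNA that silences an X chromosome in females, separated the sexes without overlap, from 3.724 to 4.326 in males and from 7.681 to 9.406 in females; 3 of its 6 probe sets did so. Genes of the X chromosome were the main other group and were mostly lower in males. Of 297 X-linked genes 36 passed, 34 of them higher in females and 2 higher in males, against 11 of 8825 genes on the other chromosomes, with Y and genes of unknown chromosome left out (12.1% and 0.125%, Fisher exact p = 4.28e-45, across genes, which are not independent). In the fixed list of X-linked genes 5 of 11 were lower in males (10 over the list alone; median -0.38, camera adjusted p = 3.87e-21, and 9.46e-05 with an estimated correlation). Besides XIST (-4.33 ± 0.25, SE) these included the translation factor EIF2S3 (-0.31 ± 0.05), the ubiquitin-activating enzyme UBA1 (-0.40 ± 0.06) and the zinc finger gene ZFX (-0.47 ± 0.06).

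In limma, 87 probe sets passed for sex, 16 higher and 71 lower in males. IDH3G, a subunit of mitochondrial isocitrate dehydrogenase, fell by 0.75 ± 0.07 (SE), IKBKG, of the NF-kappa-B pathway, by 0.63 ± 0.07, BRCC3 by 0.54 ± 0.06, UBL4A by 0.52 ± 0.05 and the complex I subunit NDUFA1 by 0.40 ± 0.05, all X-linked. On chromosomes other than X and Y, 9 genes were lower in males. The largest falls among these 9 were those of ECH1, a peroxisomal and mitochondrial enzyme of fatty acid oxidation (-1.31 ± 0.16, adjusted p = 0.00119), TSPAN32 (-1.13 ± 0.19) and TRIM52 (-0.61 ± 0.10). Higher in males were the X-linked NUDT10 (1.29 ± 0.20) and TMSB15B (1.01 ± 0.19), LOC100335202, which the RefSeq table places on Y (1.11 ± 0.12), the oestrogen sulfotransferase SULT1E1 (1.06 ± 0.18) and the trophoblast transcription factor ETS2 (0.79 ± 0.16, adjusted p just under the threshold at 0.05). MAFF stood at 0.96 and did not pass (adjusted p = 0.0549). In 118 probe sets the sexes did not overlap (0.491%, against 0.0666% by chance). The probe sets of TSPY, from -0.16 to 0.13, and of ZFY, at 0.04, did not separate the sexes. ZFY had a mean of 2.56, near the lowest value of any probe set, so it could not show a difference. These 2 genes thus say little about the sex labels. The count was 49 without the Grade 1 conceptus of no length and 52 without Grade 3 replicate 2. ETS2, TMSB15B, SULT1E1, TSPAN32, TRIM52 and UBA1 lost their calls in 12, 10, 4, 3, 2 and 1 of 14 fits with 1 conceptus left out, with a highest adjusted p of 0.163, 0.142, 0.0643, 0.0719, 0.0689 and 0.0597. Those came without Grade 1 short replicate 2 for ETS2 and SULT1E1, the conceptus of no length for TMSB15B and TSPAN32, and Grade 3 replicate 2 for TRIM52 and UBA1.

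At the preset correlation 4 other lists were higher in males. These were apoptosis and stress (median 0.05, camera adjusted p = 0.0162), adhesion (0.04, 0.0247), prostaglandins (0.07, 0.0247) and trophectoderm (0.03, 0.0481), with adjusted p = 0.152, 0.528, 0.383 and 0.152 with an estimated correlation. Sex was spread unevenly over the title prefixes, so these differences cannot be told apart from a factor behind the prefixes. Grade 3 replicates 2 (female) and 3 (male) share a prefix. There adhesion scored -0.003 and -0.02 and apoptosis 0.11 and -0.03, against the calls. Prostaglandins (0.03 and 0.18) and trophectoderm (-0.003 and 0.06) went with them. Another prefix held the female Grade 1 long replicate 2 and, as males, the conceptus of no length, short replicate 2 and long replicate 1. In that order, adhesion scored 0.175 against -0.026, 0.0007 and 0.213. Apoptosis scored 0.0595 against 0.0567, 0.145 and -0.0134, and prostaglandins 0.187 against 0.135, 0.13 and 0.345. In these lists the males lay on both sides of the female. Trophectoderm, at -0.00786 against 0.0207, 0.174 and -0.0035, went with its call. ETS2 in the trophectoderm list was the only member of these 4 lists past the threshold. Adjusted over the list alone, 2 trophectoderm genes, 1 prostaglandin gene and 1 adhesion gene were higher and 1 adhesion gene lower. Leading members were CDKN1A (1.08), PLAU (1.46) and HPGD (1.20, adjusted p = 0.0955), and none of these passed. Calls were lost without Grade 1 short replicate 1 (adhesion 0.0785, trophectoderm 0.113), short replicate 2 (prostaglandins and apoptosis 0.0692, trophectoderm 0.176) and long replicate 1 (prostaglandins 0.131, adhesion 0.197, trophectoderm 0.0513). The same held without short replicate 5 (trophectoderm and adhesion 0.0834, prostaglandins 0.0984) and long replicate 4 (both 0.0516 for trophectoderm and adhesion). Single losses came without short replicate 4 for prostaglandins (0.0811), and without long replicate 2 and short replicate 3 for trophectoderm (0.0534 and 0.0737). In the remaining 18 tested lists the smallest camera adjusted p was 0.0745, for oxidative phosphorylation. Among them the binucleate and hormone list held SULT1E1 as 1 of 19 genes (1 higher and 1 lower over the list alone) and the oxidative phosphorylation list NDUFA1 as 1 of 33 by both counts. Over the list alone 1 transport gene was higher and 1 interferon-stimulated gene lower.

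The leading members of the other lists did not pass for sex. In males the amino acid transporter SLC38A2 stood at 0.68 (adjusted p = 0.109), the mesoderm regulator SNAI1 at 0.59, the Kunitz-type protein TKDP4 at 0.35, the haemoglobin gene HBM at 0.12 and DNMT3B at 0.11. On the other side were the milk and epithelial protein LTF (-0.43), NSDHL (-0.37), the interferon response factor IRF9 (-0.29), CD3D of T cells (-0.22), DGAT1 (-0.22), FGFR4 (-0.21) and the endoderm regulator HNF4A (-0.18). Smaller still were IMPACT (-0.17), PFKM (-0.17), CD34 (-0.16), BUB1B (-0.13), PAG15 (-0.11) and COL6A1 (-0.11). Other probe sets of FGFR4, DNMT3B, CD3D and TSPY had the opposite sign without passing. Median, mean and test differed in sign for the binucleate, matrix, glycolysis, imprinted and blood lists. IFNT2 differed by 0.00 between the sexes (adjusted p = 0.995).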

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

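The tests of unequal numbers of males, of the long conceptuses among Grade 1 and of the conceptus whose labels disagree were chosen only after the results were seen. In 214 groups of values, 9 (4.21%) held a conceptus far from the rest, the gap to its nearest neighbour divided by the group's range being above Dixon's 95% limit; chance does this in about 1 in 20 groups. Among short Grade 1 conceptuses these were CDC6 in replicate 3 (gap 0.783; 8.834, nearest 9.158), TKDP2 in replicate 2 (0.778; 4.942 and 4.262), PTGIS in replicate 5 (0.905; 6.749 and 7.903) and the cholesterol list in replicate 2 (0.738; -0.07 and -0.16). In long Grade 1 conceptuses it was the glycoprotein list in replicate 1 (0.783; 0.07 and 0.13). Among males these were NSDHL in Grade 1 long replicate 1 (0.681; 9.769 and 9.492), and in Grade 1 short replicate 1 UBL4A (0.686; 10.6 and 10.46) and LTF (0.655; 3.422 and 3.583). Among females it was UBL4A in Grade 1 long replicate 3 (0.637; 10.87 and 10.96). Whether the length or grade difference itself differs between the sexes stays open, since 1 long conceptus was male and 1 Grade 3 conceptus female; limma called 0 probe sets for each (918 and 1125 at unadjusted p under 0.05; smallest adjusted p = 0.73 and 0.471).

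Long and short conceptuses differed in 1577 probe sets. Of 100 of the 126 splits of the 10 conceptuses, 1, the real one, reached that count, and the highest other had 2. That is the smallest share 100 splits can give, and the splits treat conceptuses as independent. A count this large is thus unlikely by chance, but chance is not excluded. For the 5 lists, 14 splits gave as many and the highest other had 9, so chance cannot be excluded either. Inside the prefixes, the direction was the same in 87.5% of the probe sets called outside in the lower of the 2 prefixes. The median change there was smaller inside than outside (0.52 and 0.865, and 0.472 and 0.898 in the other prefix). The probe sets were selected by their change outside, which enlarges the outside median. A smaller change inside would thus arise with or without an effect of the prefix and does not bear on it. The shared direction goes only weakly against shared title prefixes as the whole cause. Each of the 2 prefixes sets 1 conceptus against 2, and probe sets that move together are not separate observations. Unequal numbers of males are argued against by the 1556 of 1577 probe sets called in the same direction with sex as a covariate. With prefix as a fixed block, where only 2 prefixes hold both lengths, 112 were called, 85 of them shared, so part of the difference could still go with an unknown factor behind the prefixes. A difference tied to length itself, in gene activity or in the share of each tissue, stays open and was not tested.

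The cholesterol synthesis list was called lower in Grade 3 than in Grade 1 by camera at the preset correlation alone, with 0 of its 14 genes past the threshold. Of 100 of the 364 splits, 78 gave as many as the 1 list called and the highest other had 9, so chance cannot be excluded. A candidate explanation is the 5 long conceptuses among Grade 1, since the list's mean difference from short Grade 1 alone was 0.02 (0.02374, exact p = 0.554) and from long Grade 1 alone -0.386. Not every Grade 3 conceptus was like the short ones, however. On the length axis described below they lay at 0.533, 0.287 and 0.673. Short conceptuses lay between -0.346 and 0.366, a range that holds Grade 3 replicate 2 (0.287), and the lowest long conceptus lay at 0.651. The Grade 3 conceptus at 0.673 scored -0.13 for the list, while the lowest long one scored 0.07. For single probe sets the real count was 0, so the 100 of 100 splits that reached it were fixed in advance and say nothing about chance; the highest other had 515, with Grade 1 short replicates 3, 4 and 5 as the group of 3, all female, which points to a structure of the samples; whether length, sex or another factor lies behind it was not tested. Grade 3 conceptuses carry no length in the labels, so an effect of grade through length or apart from it stays open.

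Grade 1 short replicate 1 carries both length labels. Each conceptus was placed on an axis of 200 probe sets that runs from short, at 0, to long, at 1, taken from a fit without it. The probe sets and the ends of the axis thus vary between conceptuses. Grade 1 short replicate 1 lay at 0.366, above the other short conceptuses (-0.346 to 0.273) and below the long ones (0.651 to 1.31). The others were placed by fits that counted it as short, so their ranges depend on that label. A wrong length label and a conceptus of middling length cannot be told apart here, since the position lies outside both groups. With it counted as long 492 probe sets were called, 330 of them shared with the 1577, and with it left out 1697.

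For sex, 1 of 100 of the 3003 splits, the real one, reached 87 probe sets and the highest other had 28. Again this is the smallest share 100 splits can give, and conceptuses are treated as independent. The count is thus unlikely by chance, but chance is not excluded. For the 5 lists called for sex, 15 splits gave as many and the highest other had 6, so chance cannot be excluded either. Most title prefixes hold 1 sex only. For genes off the sex chromosomes, sex and a factor behind the prefixes cannot be fully told apart.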

How the results depend on the processing

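Grade against short or long Grade 1 alone for lists, and length without the 2 short conceptuses that stood most apart, were tests chosen only after the results were seen. For grade, no probe set was called under the alternatives tried except 12 at unadjusted p under 0.01 and 1.5 fold, at most 1 in sets of 4 Grade 1 conceptuses (0 in 95 of 100), and 0 to 2 with each conceptus left out (2 without Grade 3 replicate 1, 1 without Grade 1 long replicate 5). The 1 list called became 0 with an estimated correlation, with fry, with the probe set of smallest p, with sex as a covariate and against short Grade 1 (mean reversed, 0.02374), and 0 to 2 with 1 conceptus left out (0 without Grade 3 replicate 1). Against short Grade 1, TKDP2 (0.2054) and IFNT2 (0.02386), neither called, also reversed. For length, 1577 became 691 without moderation, 2403 with sex as a covariate (1556 shared), 492 with the conceptus whose labels disagree counted as long, 112 with the prefix as a fixed block, 468 without 2 short conceptuses, 2753 at adjusted p under 0.10, 554 at unadjusted p under 0.01 and 1.5 fold, and 460 to 1697 with 1 conceptus left out (655, 532, 914 and 510 without long replicates 1, 2, 4 and 5; 460 and 704 without short replicates 4 and 5). A filter gave 2070, quantile normalisation 1466 (743 higher), centring 1548, a trend with a robust prior 1791, 1 probe set per gene 1206 and a random block 1653. The 5 lists became 0 with an estimated correlation, 3 with fry, 3 with a random block, and 2 to 7 with 1 left out (3 without long replicate 1, 2 without long replicate 3 or short replicate 4). Of 49 called genes 28 were called with each conceptus left out, 17 were lost in 5 or more of 10 fits, and none reversed. The call was lost by 34 of the 49 with the prefix as a fixed block, 35 with the conceptus whose labels disagree counted as long, 26 without 2 short conceptuses, 23 without moderation, and 0 to 5 in the other alternatives at the same threshold. TSPY, not called, ran from -0.004155 (without short replicate 4) to 0.06194. For sex, 87 became 49 to 126 with 1 left out (49 without the conceptus of no length, 52 without Grade 3 replicate 2); the 5 lists became 1 with an estimated correlation, 1 with fry, 2 with the probe set of smallest p, and 2 to 7 with 1 left out (2 without short replicate 2; 3 without long replicate 1, long replicate 4 or short replicate 5). Of 17 genes called for sex, 5 lost the call without moderation, 2 (ETS2 and TMSB15B) with a random block and with grade and length as covariates, and 0 or 1 in the other alternatives with all conceptuses. IFNT2 between the sexes, not called, was 0.009679 with grade and length as covariates and ran from -0.02511 to 0.01654 with 1 left out. Apart from the fewer samples with a conceptus left out, the cause was not tested. Arrays limit what is seen at low signal, where values are compressed, and may do so at the top, where IFNT2 itself gave the highest value, 14.61.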

Other observations

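All tests of gene families here, which group genes by the stem of their symbol, were chosen only after the results were seen. Of 125 families with at least 8 genes, 14 passed camera at the preset correlation for length, 13 of them lower in long conceptuses; with an estimated correlation 0 did, and with fry 37. Mitochondrial ribosomal proteins of the large subunit (MRPL) had a negative difference in all 43 genes measured, with 13 called and a median of -0.22 (adjusted p = 9.99e-11; with an estimated correlation p = 0.0343 and adjusted p = 0.64). Those of the small subunit (MRPS) had a negative difference in 23 of 24 genes with 8 called (median -0.21), RNA polymerase subunits (POLR) in 26 of 26 with 7 called (-0.215), nucleoporins (NUP) in 20 of 20 with 2 called (-0.22) and translation initiation factors (EIF) in 35 of 40 with 7 called (-0.14). The family higher in long conceptuses was the annexins (ANXA), with 4 of 10 genes called and a median of 0.37 (adjusted p = 0.000286). Each of these directions was the same with arrays normalised once more and with arrays centred. For grade 0 families passed at the preset correlation, and for sex 1 did (ASB, lower in males, adjusted p = 0.0267, and 0.964 with an estimated correlation).

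On an axis of 200 probe sets from short, at 0, to long, at 1, fitted to all conceptuses with a length, the Grade 3 conceptuses lay at 0.533, 0.287 and 0.673 and the Grade 1 conceptus with no length at 0.498. On the first principal component they scored 3.722, -10.88, 6.553 and 1.777.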
